A study of Homo sapiens with 17 samples.

How the data were processed

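Expression was measured by the authors on 17 Affymetrix arrays with biotin-labelled total RNA from 184A1, an established non-tumorigenic line of human mammary epithelial cells. Per the labels, cells without growth factors for 16 h received epidermal growth factor (EGF) for 1 h from time 0, were washed, and spent 7 h in medium without growth factors. A second EGF pulse of 1 h, or a mock pulse, then began at 480 min. The labels give 1 array per condition and time and name the array at time 0 as the control.

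The deposited values are log2 probe-set summaries that the authors made with Affymetrix Expression Console and RMA (background correction, quantile normalization and median polish), with hg18 named as the genome build. Versions, the annotation release and whether all arrays were summarised together are not stated in the sources used here. The table holds 33297 probe sets with values from 1.14 to 13.01 and 0 missing values. Array medians lay between 4.74 and 4.84. Coordinates are not printed, because the build of the arrays' annotation and that of the reference used here differ.

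Of the probe sets, 19460 carried 1 gene symbol, 1754 carried several and 12083 were not listed in the annotation. The 1-symbol probe sets gave 18417 genes, of which 769 had more than 1 probe set and kept the one with the highest mean over the arrays. A gene was tested when its highest value exceeded 5.46, the median of all gene values, which left 10053 genes. Probe sets with no symbol or several symbols entered 1 count in the closing section only.

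Arrays were grouped by label into start (0 min, 1 array), the early window after the first pulse (30, 60, 120 and 180 min), the late window (300, 360, 420 and 480 min), the second pulse and the mock pulse (510, 540, 600 and 660 min each). Differences are on the log2 scale, with the moderated standard error (SE) from limma 3.58.1 in R 4.3.3. The second pulse was compared with the mock pulse on 8 arrays with sampling time as a block, which left 3 residual degrees of freedom and a prior of 7.4. The change of that effect between the earlier times (510 and 540 min) and the later times (600 and 660 min) had 2 residual and 8.9 prior degrees of freedom. The other contrasts came from 1 fit of all 17 arrays in 5 groups with a term for minutes since the pulse (30, 60, 120, 180) and had 9 residual and 5.8 prior degrees of freedom. The start group is a single array, so its spread was taken from the other groups. Calls are limma's Benjamini-Hochberg adjusted p-values under 0.05 over 10053 genes, and all tests are two-sided. Differences at single times carry no p-value. For these, genes that differed by 1 or more on the log2 scale were counted, and the same count between neighbouring arrays without EGF served as background. No such pair holds the start array, so mock arrays against the start were counted as well.

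The sampling times are not replicates. Nothing in the labels marks separate cultures for a given time, so p-values measure only the spread between sampling times of single arrays. The number of arrays limits the precision.

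Groups, contrasts, the rule for naming genes, 25 gene lists with 387 genes (350 measured) and the alternative settings were fixed before the data were examined. The lists cover immediate early genes, feedback regulators, ErbB ligands, ErbB receptors, p53 targets, FOXO targets, EGR1 targets, ribosome biogenesis, nucleotide synthesis, glycolysis, cholesterol synthesis, fatty acid synthesis, amino acid stress, G1/S, G2/M, NF-kB and cytokine genes, interferon response, matrix and migration, basal epithelium, luminal epithelium, squamous differentiation, fibroblasts, endothelium, leukocytes and housekeeping. Lists share some genes. Lists with at least 3 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated from the data. With the estimated correlation 0 of 60 list calls held. Medians at single times were placed among those of 10000 random lists matched on expression.

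The text names, for the mean effect of the second pulse, up to 10 of the largest rises and 10 of the largest falls with 1 direction at all 4 times. For other tested contrasts it takes 6 each way, at single times 3 each way, and of each list up to 4 of the called members with the largest change. EGR1, FOS, MYC, CDKN1A, MDM2, EGFR, HBEGF, DUSP6, CCND1, NAB2 and SPRY4 were always included. From the genes so chosen the text prints a part.

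Alternatives covered the expression filter, scaling between arrays, the treatment of several probe sets, the limma prior, the time term, the arrays in the fit, the baselines, the fold threshold and leaving out each sampling time. The tests were checked on simulated data with 10053 genes: a change of 1 on the log2 scale was recovered for 92.5% to 100% of genes in the 7 contrasts, and a change of 0.5 for 16.4% to 94.0%. Of 9833 genes simulated without a change, 7 to 15 were called. Simulated changes were equal at all times of a compared group, and noise was independent between genes. The recovery rates therefore do not apply to genes with short peaks. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.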

Results

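The data are log2 expression values from 17 arrays that follow 184A1 mammary epithelial cells through EGF pulses that began at 0 and 480 min. There was 1 array at the start, 4 in the early window after the first pulse (30 to 180 min), 4 in the late window (300 to 480 min), 4 after the second pulse (510 to 660 min) and 4 after a mock pulse at the same times. Per the title of the series, the study asks how cells treat a first and a second mitogenic signal and what p53 and EGR1 do there. Arrays resembled each other closely. The mean correlation of an array with the others, across probe sets, ran from 0.992 for the 180 min array and 0.993 for the start array to 0.994. There are no replicate arrays, and errors below are standard errors of the fitted log2 difference.

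Cytokine and immediate early genes were higher in the early window after the first EGF pulse than on the start array (4 arrays against 1). The first pulse was compared without a mock arm, so EGF and handling are not told apart here, and after the later mock pulse alone FOS differed by 3.12 and EGR1 by 2.04. IL6, a cytokine, read 3.63 at the start, below the 5.46 of the filter, and rose by 3.52 ± 0.69 (adjusted p = 0.0080). The orphan nuclear receptors NR4A2 and NR4A1 rose by 3.30 ± 0.66 (adjusted p = 0.0091) and 2.81 ± 0.37 (adjusted p = 9.13e-04). RGS2, a brake on G-protein signalling, rose by 2.68 ± 0.41, the AP-1 factor FOSB by 2.32 ± 0.35, and CD55, which protects cells from complement, by 2.30 ± 0.39. In all, 644 genes were higher and 325 lower, with 2656 at an unadjusted p under 0.05. The largest falls were smaller and included FHOD1, an actin regulator, at -0.87 ± 0.16, the melanosome transport protein MLPH at -0.86 ± 0.17, and the receptor tyrosine kinase MST1R at -0.85 ± 0.19.

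Of 23 tested immediate early genes, 11 were called higher in the early window, and 13 when adjusted over the list alone. Their median difference was 0.83 (camera adjusted p = 1.98e-08, adjusted p = 0.300 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 2.06 ± 0.41. Feedback regulators had 6 of 21 called higher (7 adjusted over the list alone) and a median of 0.26 (adjusted p = 0.0129, adjusted p = 0.481 with an estimated correlation, and 0.0628 with the term for sampling time left out). Among them TNFAIP3, an inhibitor of NF-kB, rose by 2.06 ± 0.40, the MAP kinase phosphatases DUSP1 and DUSP5 by 2.04 ± 0.42 and 1.71 ± 0.35, and SOCS3, an inhibitor of cytokine signalling, by 1.10 ± 0.22. Of 5 ErbB ligands, 3 were called higher (3 adjusted over the list alone), with a median of 0.88 (adjusted p = 0.0015, adjusted p = 0.300 with an estimated correlation). HBEGF rose by 1.65 ± 0.39 and NRG1 by 1.21 ± 0.21. NF-kB and cytokine genes had 5 of 13 called higher (11 adjusted over the list alone) and a median of 1.16 (adjusted p = 2.06e-05, adjusted p = 0.300 with an estimated correlation), with the chemokine CCL20 at 1.74 ± 0.32.

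The lists of G2/M genes and p53 targets also passed as higher than on the start array. Of 20 G2/M genes, 11 were called higher (14 adjusted over the list alone), with a median of 0.38 (adjusted p = 8.40e-09, adjusted p = 0.300 with an estimated correlation). The mitotic motor KIF11 rose by 0.84 ± 0.15, the spindle protein NUSAP1 by 0.84 ± 0.11 and the topoisomerase TOP2A by 0.71 ± 0.11. Of 24 p53 targets, 5 were called higher (8 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.0023, adjusted p = 0.300 with an estimated correlation). The kinase PLK2 rose by 1.04 ± 0.23 and RRM2B, a subunit of ribonucleotide reductase, by 0.73 ± 0.11. CDKN1A, the cell cycle inhibitor p21, stood at 0.09 ± 0.14 (adjusted p = 0.736) and MDM2, which targets p53 for degradation, at 0.17 ± 0.14 (adjusted p = 0.457).

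The lists of nucleotide synthesis, ribosome biogenesis and G1/S genes passed as lower than at the start. Of 14 nucleotide synthesis genes, 6 were called lower (9 adjusted over the list alone), with a median of -0.30 (adjusted p = 6.37e-06, adjusted p = 0.300 with an estimated correlation). PFAS, of purine synthesis, stood at -0.58 ± 0.11 and CAD, of pyrimidine synthesis, at -0.48 ± 0.12. The list as fixed also holds SRM and ODC1, enzymes of polyamine synthesis, and SRM was called lower at -0.53 ± 0.10. Of 24 ribosome biogenesis genes, 3 were called lower (3 adjusted over the list alone), with a median of -0.17 (adjusted p = 3.08e-04, adjusted p = 0.440 with an estimated correlation). G1/S genes had 8 of 24 called lower (10 lower and 1 higher adjusted over the list alone). Their median was -0.25 (adjusted p = 3.70e-06, adjusted p = 0.373 with an estimated correlation). CDT1, which licenses replication origins, was at -0.81 ± 0.17 and CCNE1, cyclin E1, at -0.54 ± 0.10. Not passing were basal epithelium (adjusted p = 0.0513), cholesterol synthesis (0.0949, with 2 of 17 called higher), EGR1 targets (0.184), luminal epithelium (0.297), amino acid stress (0.341) and matrix and migration (0.341). Fatty acid synthesis (0.483, with 1 of 8 called higher), FOXO targets (0.483), glycolysis (0.919), interferon response (0.919), housekeeping (0.919) and fibroblasts (0.948) did not pass either. ErbB receptors and squamous differentiation had 2 tested members each, leukocytes 1 and endothelium 0, too few for a list test.

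The early values averaged over genes with short peaks. EGR1, the zinc finger factor named in the title, read 8.41 at the start, 10.10 at 30 min, 10.26 at 60 min and 6.27 at 180 min, and its window mean differed from the start by 0.18 ± 0.61 (adjusted p = 0.8796). FOS, the AP-1 factor, read 8.30 at the start, 10.94 at 30 min and 7.30 at 180 min, with a window difference of 0.83 ± 0.61 (adjusted p = 0.407). DUSP6, an ERK phosphatase, read 7.66 at the start and no higher than 7.30 at 30 to 180 min. At 480 min EGR1, FOS and DUSP6 differed from the start by -2.28, -1.91 and -2.27. Their first responses thus depend strongly on the level of that 1 array. Every early comparison rests on the single start array, and without the 120 min array 595 genes were called. With quantile normalization 576 genes were higher and 469 lower, and of 60 named gene calls 48 passed with any 1 of the 4 early arrays left out.

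**Figure D1:**
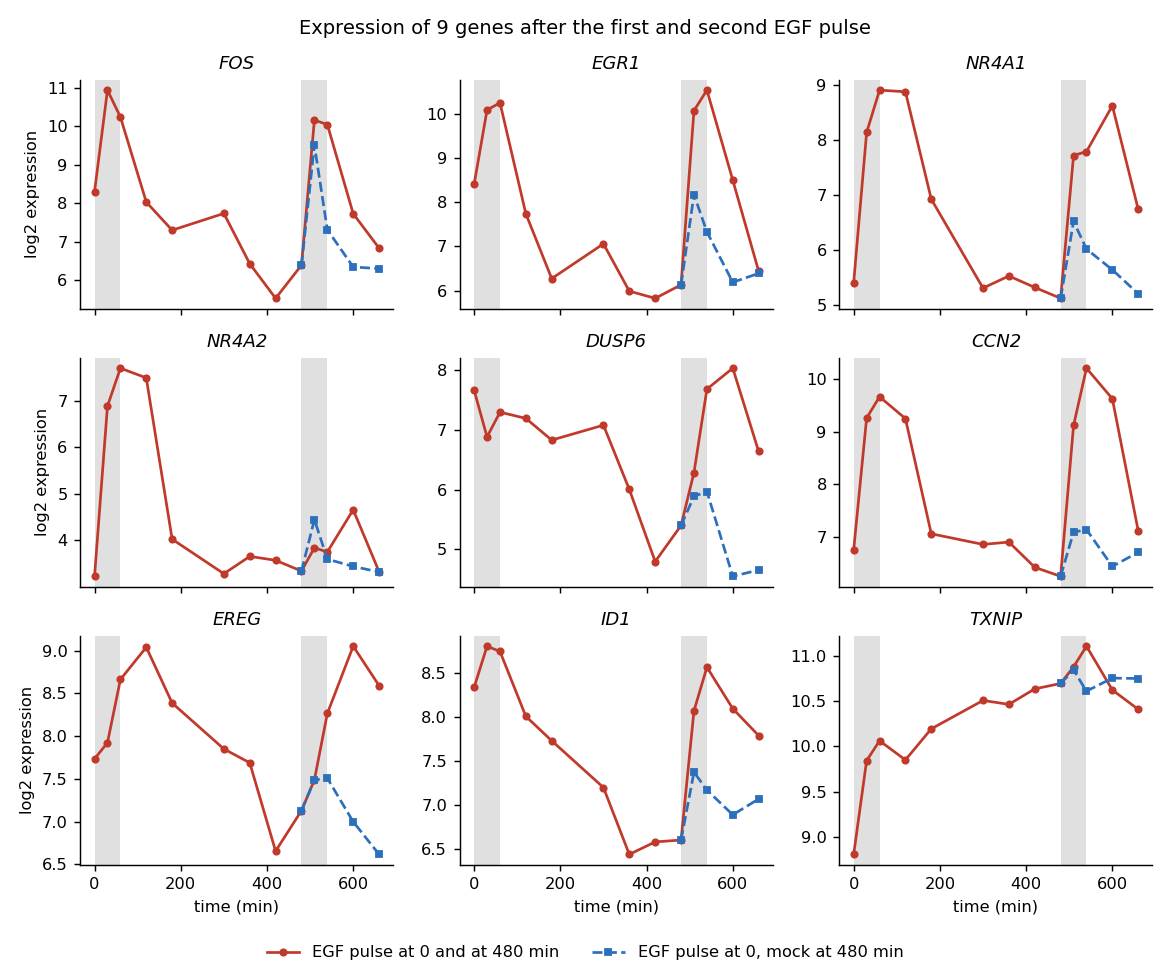
Log2 expression (vertical axes) against minutes after the start of the first pulse (horizontal axes) for 9 genes, with 1 array per point, the pulsed series in red, the mock series in blue with dashes, and the 1 h pulses in grey. EGR1 rose from 8.41 to 10.26 at 60 min. At 540 min it read 10.55 in the series with the second pulse and 7.33 in the mock series.

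At single times the number of genes that stood 2-fold or more above the start array was 68 at 30 min, 91 at 60 min, 105 at 120 min, 138 at 180 min and 26 at 300 min. The corresponding falls numbered 3, 3, 4, 17 and 6. Between neighbouring arrays without EGF in the late window and mock series, 0 to 9 genes differed by that much, but none of these pairs holds the start array. Against the start, the mock arrays at 510, 540, 600 and 660 min had 41, 30, 27 and 43 genes 2-fold higher. Their genes 2-fold lower numbered 12, 14, 24 and 22. IL6 was 5.44 above the start at 60 min, NR4A2 was 4.47 above it, and at 180 min STEAP4, a metalloreductase, was 3.17 above it. At 420 min 21 genes were above and 29 below, with DUSP6 at -2.87 and FOS at -2.77. Over all 8 times 277 genes differed by 2-fold at least once (230 up, 47 down, by the largest difference of each gene). Among genes that stood 2-fold above the start at any of these times, 106 were highest at 180 min.

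**Figure D2:**
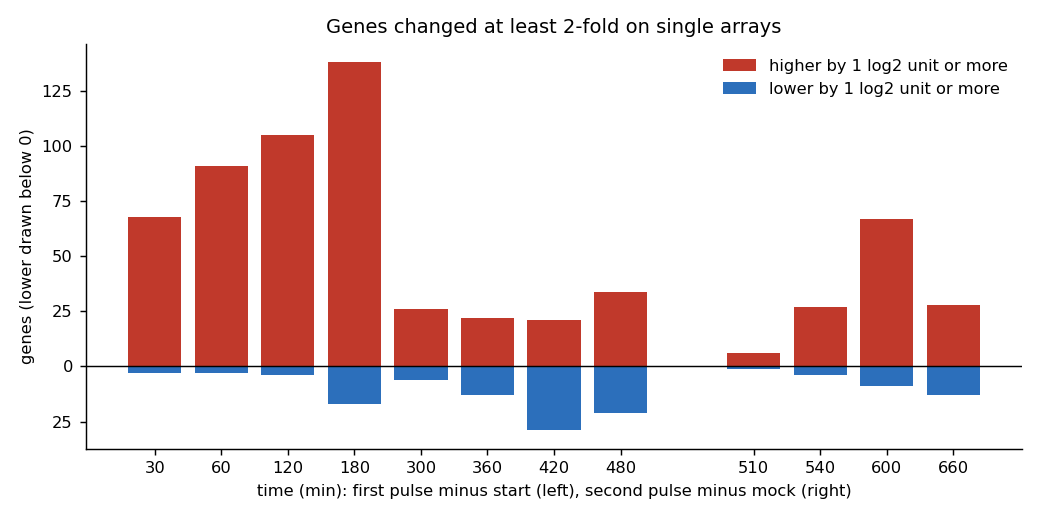
Number of genes (vertical axis) that differed by 1 or more on the log2 scale at each time (horizontal axis), for each array against the start array and for the second pulse against the mock pulse at the same time, with bars above 0 for higher and below 0 for lower genes. Counts reached 138 higher genes at 180 min for the first pulse. For the second pulse they reached 67 at 600 min, which is 120 min after that pulse began.

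In the late window after the first pulse, compared with the start array (4 arrays against 1), the largest rises were in ARRDC4 and TXNIP, related arrestin-fold proteins that restrain glucose uptake. ARRDC4 rose by 2.08 ± 0.34 (adjusted p = 0.0070) and TXNIP by 1.77 ± 0.19 (3.41-fold, adjusted p = 4.83e-04). CFLAR, an inhibitor of death receptor signalling, rose by 1.59 ± 0.24, the cadherin FAT4 by 1.43 ± 0.30 and the cytochrome CYP1B1 by 1.36 ± 0.18. ID1, an inhibitor of differentiation factors, fell by 1.64 ± 0.27 (adjusted p = 0.0068). The circadian repressor BHLHE41 was at -1.38 ± 0.26, the retinal reductase DHRS3 at -1.26 ± 0.18 and the receptor adaptor GRB7 at -1.16 ± 0.20. In all, 369 genes were higher and 215 lower, with 2283 at an unadjusted p under 0.05.

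Genes of cholesterol synthesis formed the list with the smallest p in the late window. Of 17 tested members, 7 were called higher (13 adjusted over the list alone), all 17 lay above 0, and the median was 0.38 (camera adjusted p = 5.16e-09, adjusted p = 0.291 with an estimated correlation). SC5D rose by 0.67 ± 0.13, HMGCS1 by 0.63 ± 0.13 and CYP51A1 by 0.63 ± 0.10, each an enzyme of the pathway. At single times the list median went from 0.05 at 30 min to 0.31 at 300 min and 0.45 at 420 min. ACLY, which makes the acetyl-CoA used for lipids, rose by 0.58 ± 0.09 as the 1 called member of 8 fatty acid genes (1 adjusted over the list alone, adjusted p = 0.0489, adjusted p = 0.620 with an estimated correlation). The cystine transporter SLC7A11, at 1.22 ± 0.18, was the 1 called member of 13 amino acid stress genes (1 adjusted over the list alone, median 0.18, adjusted p = 0.0257, adjusted p = 0.291 with an estimated correlation).

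G2/M genes again stood above the start array, with 8 of 20 called higher (11 adjusted over the list alone) and a median of 0.32 (adjusted p = 1.49e-08, adjusted p = 0.421 with an estimated correlation). The mitotic kinases AURKA and CDK1 were higher by 0.78 ± 0.14 and 0.66 ± 0.12. Of 24 p53 targets, 3 were called higher (3 adjusted over the list alone, median 0.18, adjusted p = 0.0387, adjusted p = 0.421 with an estimated correlation), among them RRM2B at 0.64 ± 0.11. Nucleotide synthesis had 1 of 14 called lower (3 adjusted over the list alone, median -0.16, adjusted p = 0.0068, adjusted p = 0.421 with an estimated correlation). Immediate early genes had 2 of 23 called lower (3 adjusted over the list alone, median -0.15, adjusted p = 0.0435, adjusted p = 0.640 with an estimated correlation). Feedback regulators had 1 of 21 (2 adjusted over the list alone, median -0.31, adjusted p = 0.0387, adjusted p = 0.620 with an estimated correlation). EGR1 was at -2.16 ± 0.61 (adjusted p = 0.0534), DUSP6 at -1.85 ± 0.68 (adjusted p = 0.123) and FOS at -1.78 ± 0.61 (adjusted p = 0.0984). Ribosome biogenesis had 2 of 24 called lower (3 adjusted over the list alone, adjusted p = 0.0435, adjusted p = 0.640 with an estimated correlation). G1/S had 2 lower and 1 higher of 24 (3 lower and 1 higher adjusted over the list alone, adjusted p = 0.0387, adjusted p = 0.640 with an estimated correlation). Without the 480 min array 319 genes were called. The calls for immediate early genes, feedback regulators, ribosome biogenesis, fatty acid synthesis and G1/S ended without the 420 min array (adjusted p from 0.0885 to 0.115) and without the 480 min array (0.101 to 0.165). With the term for sampling time left out these calls (0.0564 to 0.193) and the p53 call (0.0625) ended.

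The late and early windows, compared with each other (4 arrays against 4), do not rest on the start array. Of the 644 genes called higher in the early window than at the start, 302 were called lower in the late than in the early window, and 178 were also called higher in the late window than at the start. The 644 and the 178 do rest on the start array. The 302 use the early arrays in both calls, and the 178 use the start array in both. Errors of shared arrays enter both calls, so these overlaps are partly built in. IL6 fell, with a difference of -3.21 ± 0.44 (adjusted p = 2.94e-04). NR4A2 was at -3.06 ± 0.42 and NR4A1 at -2.90 ± 0.23 (adjusted p = 6.93e-06). FOS was at -2.61 ± 0.38, EGR1 at -2.34 ± 0.39 (adjusted p = 0.0012) and CCN2, a secreted matricellular protein, at -2.19 ± 0.33. The largest rises were CYP1A1, a cytochrome of xenobiotic metabolism, by 1.04 ± 0.14, ARRDC4 by 1.03 ± 0.22, TMEM156, a membrane protein, by 0.91 ± 0.20 and the replication factor TICRR by 0.89 ± 0.13. A rise of 0.87 ± 0.08 was assigned to the linker histone gene H1-1, whose close relatives make the assignment uncertain. In all, 887 genes were lower and 583 higher, with 2835 at an unadjusted p under 0.05.

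Of 23 immediate early genes, 21 were called lower (22 adjusted over the list alone), with a median of -1.197 (camera adjusted p = 2.02e-21, adjusted p = 0.0823 with an estimated correlation). Of 21 feedback regulators, 13 were called lower (14 adjusted over the list alone, median -0.73, adjusted p = 1.35e-09, adjusted p = 0.109 with an estimated correlation). DUSP5 was at -1.92 ± 0.22 and DUSP1 at -1.77 ± 0.26. NF-kB and cytokine genes had 11 of 13 called lower (11 adjusted over the list alone, median -0.94, adjusted p = 3.18e-08, adjusted p = 0.109 with an estimated correlation). Of 10 EGR1 targets, a list that includes EGR1, 6 were called lower and 1 higher (6 and 1 adjusted over the list alone, median -0.43, adjusted p = 6.26e-04, adjusted p = 0.0880 with an estimated correlation). F3, tissue factor, was at -0.90 ± 0.21 and NAB1, a corepressor of EGR1, at -0.73 ± 0.07. ErbB ligands had 3 of 5 called lower (4 adjusted over the list alone, median -0.45, adjusted p = 0.0013, adjusted p = 0.198 with an estimated correlation). HBEGF fell by 1.74 ± 0.25. Matrix and migration genes had 3 of 10 called lower (4 adjusted over the list alone, median -0.21, adjusted p = 4.70e-04, adjusted p = 0.109 with an estimated correlation). The urokinase receptor PLAUR was at -1.07 ± 0.19 and the laminin chain LAMB3 at -0.73 ± 0.10.

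Of the lists that passed as higher, cholesterol synthesis had 9 of 17 called higher (10 higher and 1 lower adjusted over the list alone, median 0.28, adjusted p = 4.11e-07, adjusted p = 0.109 with an estimated correlation). The decarboxylase MVD was at 0.61 ± 0.08. G1/S genes had 7 of 24 called higher (8 adjusted over the list alone, median 0.11, adjusted p = 4.12e-04, adjusted p = 0.404 with an estimated correlation). The replication licensing genes CDC6 and ORC1 were at 0.52 ± 0.08 and 0.47 ± 0.08. Nucleotide synthesis had 3 of 14 called higher (3 adjusted over the list alone, median 0.11, adjusted p = 0.0039, adjusted p = 0.220 with an estimated correlation). Of 12 FOXO targets, 2 were called higher and 1 lower (2 and 2 adjusted over the list alone), without a list call (adjusted p = 0.344). Fatty acid synthesis did not pass either (2 of 8 called higher and 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.156), nor did p53 targets (2 of 24 higher and 5 lower, the same adjusted over the list alone, median -0.03, adjusted p = 0.209) or G2/M genes (1 of 20 higher and 3 lower, 2 and 3 adjusted over the list alone, median -0.11, adjusted p = 0.230). Among epithelial markers, CDH3, P-cadherin, of the basal list, was at -0.30 ± 0.05 and CD24, of the luminal list, at -0.79 ± 0.13. The basal list had 2 of 5 called lower (3 adjusted over the list alone, adjusted p = 0.0125, adjusted p = 0.198 with an estimated correlation). The luminal list had 2 of 10 (4 adjusted over the list alone, adjusted p = 0.0310, adjusted p = 0.154 with an estimated correlation). Ribosome biogenesis was higher, with 0 of 24 called and 0 adjusted over the list alone (adjusted p = 0.0158, adjusted p = 0.507 with an estimated correlation). The basal call ended without the 180 min array (adjusted p = 0.0539), the luminal call without the 60 min array (0.0712) or the 360 min array (0.0638), and the ribosome call without the 30, 60, 300 or 360 min array (0.0577 to 0.113). The number of genes called fell to 940, 872 and 923 without the 30, 60 and 120 min arrays and to 799 in a fit of these 8 arrays alone, and after median centring 816 were higher and 778 lower (791 and 784 with quantile normalization).

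The mock arm was compared with the late window (4 arrays against 4) to show what changed without a second pulse. By limma 0 genes passed, with 1682 at an unadjusted p under 0.05. Lists nevertheless shifted. Ribosome biogenesis was lower (0 of 24 called, 3 adjusted over the list alone, median -0.16, camera adjusted p = 1.82e-09, adjusted p = 0.364 with an estimated correlation). So were G1/S (0 of 24 called, 0 adjusted over the list alone, median -0.10, adjusted p = 7.07e-05, adjusted p = 0.470 with an estimated correlation) and nucleotide synthesis (0 of 14 called, 0 adjusted over the list alone, median -0.10, adjusted p = 0.0095, adjusted p = 0.466 with an estimated correlation). G2/M genes were higher (0 of 20 called, 10 adjusted over the list alone, median 0.18, adjusted p = 2.90e-06, adjusted p = 0.466 with an estimated correlation). So were interferon response (0 of 10 called, 5 adjusted over the list alone, median 0.22, adjusted p = 2.54e-04, adjusted p = 0.207 with an estimated correlation) and amino acid stress (0 of 13 called, 3 adjusted over the list alone, median 0.13, adjusted p = 0.0033, adjusted p = 0.207 with an estimated correlation). Immediate early genes were higher (0 of 23 called, 0 adjusted over the list alone, median 0.23, adjusted p = 0.0297, adjusted p = 0.648 with an estimated correlation). That call ended without the mock 510 min array (adjusted p = 0.435), the mock 660 min array (0.858), the 420 min array (0.122) or the 480 min array (0.334), and with the term for sampling time left out (0.236). The nucleotide synthesis call ended without the 300 min array (0.0649). Without the 480 min array 58 genes were called.

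The mock pulse itself coincided with a short step in a few immediate early genes. From the 480 min array to the mock array at 510 min, FOS differed by 3.12, EGR1 by 2.04, ATF3, a stress-responsive factor, by 1.68, DUSP1 by 1.45, NR4A1 by 1.40, IL6 by 1.37 and NR4A2 by 1.11. These were the 7 genes with a 2-fold rise, and 0 genes had a 2-fold fall. IL6 (3.93 and 5.29) and NR4A2 (3.34 and 4.45) lay below the 5.46 of the filter on both arrays, and ATF3 (4.57) and NR4A1 (5.11) did so at 480 min. All 23 immediate early genes lay above 0, with a median of 0.52. Effects of the second pulse below are measured against the mock arrays and so leave this step out.

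The second EGF pulse raised 22 genes and lowered 2 against the mock pulse (4 arrays against 4 at the same times), and all 24 had the same direction at all 4 times. Such a shared direction is close to a condition of a call, because the test sets the mean against the spread between times. CCN2 rose most, by 2.16 ± 0.35 (4.47-fold, adjusted p = 0.0427), followed by NR4A1 at 1.88 ± 0.22 (3.67-fold, adjusted p = 0.0128). SLC20A1, a phosphate transporter, rose by 1.40 ± 0.22, DUSP5 by 1.37 ± 0.19, TUFT1, tuftelin, by 1.27 ± 0.21 and ID1 by 1.01 ± 0.12. JUN and FOSB, of the AP-1 family, rose by 0.92 ± 0.14 and 0.83 ± 0.13, LAMB3 by 0.78 ± 0.12 and MYC by 0.55 ± 0.09 (adjusted p = 0.0469). Probe sets named for the microRNAs MIR21 and MIR221 rose by 1.28 ± 0.19 and 1.03 ± 0.12. Their assignment to the mature or a longer transcript is uncertain. The falls were LIMD1-AS1, an antisense transcript, at -0.67 ± 0.10 and the histone gene H2BC21 at -0.58 ± 0.07, both of uncertain assignment.

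Several genes with large but uneven effects did not pass. DUSP6 stood at 1.90 ± 0.35 (adjusted p = 0.0798), with 0.40 at 510 min and 3.49 at 600 min. EGR1 stood at 1.87 ± 0.36 (adjusted p = 0.108), with 3.21 at 540 min and 0.05 at 660 min. FOS stood at 1.33 ± 0.28 (adjusted p = 0.125) and HBEGF at 0.98 ± 0.22 (adjusted p = 0.127). SPRY4, a Sprouty inhibitor of receptor signalling, stood at 0.74 ± 0.16 (adjusted p = 0.127), NAB2, a corepressor of EGR1, at 0.43 ± 0.10 (adjusted p = 0.149), CCND1, cyclin D1, at 0.25 ± 0.07 (adjusted p = 0.251) and EGFR, the EGF receptor, at 0.13 ± 0.07 (adjusted p = 0.485). CDKN1A was at -0.14 ± 0.10 (adjusted p = 0.611) and MDM2 at -0.03 ± 0.10 (adjusted p = 0.942).

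Of 23 immediate early genes, 10 were called higher after the second pulse (19 adjusted over the list alone), and all 23 lay above 0, with a median of 0.66 (camera adjusted p = 3.22e-33, adjusted p = 0.160 with an estimated correlation). Of 21 feedback regulators 1 was called higher and 19 adjusted over the list alone, with a median of 0.43 (adjusted p = 2.66e-27, adjusted p = 0.160 with an estimated correlation). ErbB ligands had 0 of 5 called and 5 adjusted over the list alone (median 0.41, adjusted p = 2.69e-08, adjusted p = 0.175 with an estimated correlation). EGR1 targets had 0 of 10 and 4 (median 0.31, adjusted p = 2.40e-09, adjusted p = 0.160 with an estimated correlation). This list includes EGR1 itself, also an immediate early gene, and NAB1 and NAB2, also feedback regulators. It is therefore not independent of those lists. NF-kB and cytokine genes had 0 of 13 and 6 higher with 1 lower (median 0.41, adjusted p = 5.63e-10, adjusted p = 0.217 with an estimated correlation). Matrix and migration genes had 1 of 10 and 5 (median 0.30, adjusted p = 2.69e-08, adjusted p = 0.160 with an estimated correlation). Ribosome biogenesis was slightly higher, with 0 of 24 called and 0 adjusted over the list alone (median 0.09, adjusted p = 3.17e-05, adjusted p = 0.481 with an estimated correlation).

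G2/M genes were lower after the second pulse, with 0 of 20 called and 5 adjusted over the list alone (median -0.16, adjusted p = 3.68e-04, adjusted p = 0.289 with an estimated correlation). Amino acid stress genes were also lower, with 0 of 13 called and 2 adjusted over the list alone (median -0.12, adjusted p = 0.0057, adjusted p = 0.289 with an estimated correlation), a call that ended without the 660 min pair (adjusted p = 0.106). The p53 targets did not pass (0 of 24 called, 2 higher and 3 lower adjusted over the list alone, median -0.08, adjusted p = 0.892). FOXO targets (adjusted p = 0.111), cholesterol synthesis (0.308), G1/S (0.369), housekeeping (0.369), interferon response (0.391), basal epithelium (0.401), glycolysis (0.5003), fibroblasts (0.619), fatty acid synthesis (0.772), luminal epithelium (0.957) and nucleotide synthesis (0.957) did not pass either. The number of genes called depended on single times: 58 without the 510 min pair, 0 without the 540 min pair and 2 without the 600 min pair, so that 0 of the 15 named calls held in every fit. It was also 1 with sampling time left out of the model, 8 with the stricter filter, and 11 with median centring, where all 24 genes kept their direction.

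At single times, 6 genes were 2-fold higher and 1 lower at 510 min, 27 and 4 at 540 min, 67 and 9 at 600 min, and 28 and 13 at 660 min, against 0 to 9 between neighbouring arrays without EGF. At 600 min DDIT4, an inhibitor of mTOR signalling, was at -1.36, BCL6, a transcriptional repressor, at -1.27 and ID3, an inhibitor of differentiation factors, at -1.196. At 660 min ID3 was at -1.52 and SCNN1G, a sodium channel subunit, at -1.66. The median of the p53 targets was -0.06 at 510 min, -0.05 at 540 min and -0.01 at 600 min, at percentiles 22.1, 35.4 and 95.1 of 10000 random lists. At 660 min it was -0.25, with 7 of 24 above 0, below all random lists, and CDKN1A was at -0.54. That is 1 array against 1, and random lists of unrelated genes ignore correlation within the list.

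The effect of the second pulse was then compared between the later times (600 and 660 min) and the earlier times (510 and 540 min). FST, which binds activin, was raised more at the later times, by 1.80 ± 0.23 (adjusted p = 0.0240). The ligand EREG differed by 1.64 ± 0.21, ANGPTL4, an inhibitor of lipoprotein lipase, by 1.61 ± 0.20, PHLDA1 by 1.54 ± 0.21, the integrin ITGA2 by 1.42 ± 0.19 and the scaffold AKAP12 by 1.12 ± 0.15. BCL6 differed by -1.05 ± 0.16 (adjusted p = 0.0414). In all, 9 genes differed upward and 1 downward, with 700 at an unadjusted p under 0.05.

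ErbB ligands had 1 of 5 called higher at the later times (3 adjusted over the list alone, median 0.76, camera adjusted p = 1.22e-05, adjusted p = 0.648 with an estimated correlation). Feedback regulators had 1 of 21 (8 higher and 1 lower adjusted over the list alone, median 0.27, adjusted p = 1.62e-07, adjusted p = 0.663 with an estimated correlation). Matrix and migration genes had 1 of 10 (4 higher and 1 lower adjusted over the list alone, median 0.38, adjusted p = 0.0017, adjusted p = 0.648 with an estimated correlation). FOXO targets were lower, with 1 of 12 called (3 lower and 1 higher adjusted over the list alone, median -0.29, adjusted p = 0.0055, adjusted p = 0.663 with an estimated correlation). Ribosome biogenesis was higher (0 of 24 called, 0 adjusted over the list alone, adjusted p = 0.0097, adjusted p = 0.977 with an estimated correlation) and amino acid stress lower (0 of 13 called, 0 adjusted over the list alone, adjusted p = 0.0326, adjusted p = 0.663 with an estimated correlation). Immediate early genes did not pass as a list (adjusted p = 0.901). Nor did p53 targets (0 of 24 called, 0 adjusted over the list alone, median -0.10, adjusted p = 0.214, adjusted p = 0.977 with an estimated correlation). The number of genes called was 26 without the 540 min pair, 0 without the 600 min pair and 2 without the 660 min pair. The feedback call ended without the 600 min pair (0.109), the FOXO call without 660 min (0.130), ribosome biogenesis without 510 or 660 min (0.420 and 0.257), and amino acid stress without 540 or 660 min (0.0982 and 0.185).

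**Figure D3:**
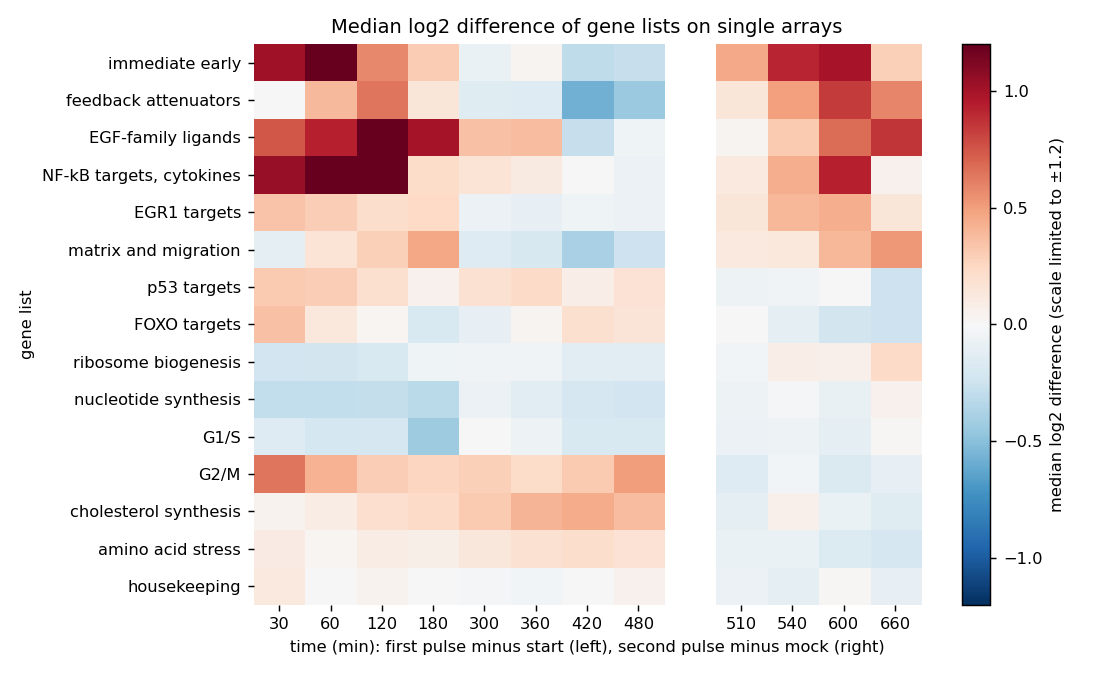
Median log2 difference (colour, limited to 1.2 either way) of 15 gene lists (vertical axis) at each time (horizontal axis), against the start array after the first pulse and against the mock array after the second. The median of immediate early genes was 1.33 at 60 min and 0.99 at 600 min, and that of cholesterol synthesis was 0.45 at 420 min.

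The responses to the pulses, first pulse against start and second pulse against mock, were compared at matched minutes. NR4A2 responded more to the first pulse, by 3.10 ± 0.79 (adjusted p = 0.0439), as did RGS2, by 2.25 ± 0.48 (adjusted p = 0.0237), STEAP4, by 1.84 ± 0.38. So did CFLAR, by 1.69 ± 0.28, the thrombin receptor F2R, by 1.63 ± 0.16 (adjusted p = 2.86e-04), and IL1RN, the interleukin 1 receptor antagonist, by 1.503 ± 0.21. NR4A2 read 7.70 at 60 min against 3.23 at the start, and 3.75 at 540 min against 3.60 after the mock pulse. Of these 4 values 3 lie below the 5.46 of the filter, as do the start values of RGS2 (4.55), STEAP4 (3.72) and IL1RN (4.04). The difference was negative for the receptor TLR4, at -1.40 ± 0.37, and for NOG, an antagonist of bone morphogenetic proteins, at -1.04 ± 0.23. In all, the difference was above 0 for 294 called genes and below 0 for 82 (210 and 113 with median centring, 209 and 142 with quantile normalization), with 2133 at an unadjusted p under 0.05. All 294 had a first response above 0, and 227 of them a second effect below 0. All 82 had a first response below 0, of which 75 were called lower in the early window than at the start, and 58 had a second effect above 0. These genes were chosen by the difference itself, so the signs partly follow from the choice. Over all 10053 genes the median second effect was -0.03. EGR1 (-1.69 ± 0.73, adjusted p = 0.197), FOS (-0.50 ± 0.72, adjusted p = 0.732), MYC (-0.50 ± 0.27, adjusted p = 0.290) and DUSP6 (-2.51 ± 0.81, adjusted p = 0.0954) did not pass.

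G2/M genes had the smallest camera p of the lists, with 9 of 20 called (18 adjusted over the list alone), all 20 above 0, and a median of 0.53 (camera adjusted p = 4.80e-12, adjusted p = 0.300 with an estimated correlation). NUSAP1 differed by 1.04 ± 0.13 (adjusted p = 0.0016). Of 24 p53 targets, 4 were called above 0 (5 adjusted over the list alone, median 0.28, adjusted p = 0.0027, adjusted p = 0.300 with an estimated correlation), among them SPATA18 at 0.68 ± 0.11 and RRM2B at 0.64 ± 0.13. Ribosome biogenesis had 3 of 24 below 0 (3 adjusted over the list alone, median -0.23, adjusted p = 1.50e-07, adjusted p = 0.346 with an estimated correlation). Nucleotide synthesis had 1 of 14 (6 adjusted over the list alone, median -0.22, adjusted p = 9.90e-06, adjusted p = 0.300 with an estimated correlation), and G1/S had 1 of 24 (6 lower and 1 higher adjusted over the list alone, median -0.24, adjusted p = 3.92e-05, adjusted p = 0.519 with an estimated correlation). Cholesterol synthesis had 1 of 17 above 0 (2 adjusted over the list alone, median 0.17, adjusted p = 0.0397, adjusted p = 0.519 with an estimated correlation), and NF-kB and cytokine genes 0 of 13 (0 adjusted over the list alone, median 0.71, adjusted p = 0.0495, adjusted p = 0.526 with an estimated correlation). Immediate early genes did not pass as a list (2 of 23 called, 4 adjusted over the list alone, adjusted p = 0.493), nor did feedback regulators (0 of 21, 0 adjusted over the list alone, adjusted p = 0.156).

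The count of genes that differed between the pulses fell to 188 without the 120 min array, 202 without the 510 min pair and 71 without the 600 min pair, and to 154 with the 480 min array as baseline of the second pulse. With the late window as baseline of the first pulse it was 332, of which 97 were shared, 340 of the 376 kept their direction, and the median difference over the 294 genes was 0.474 of the original. Of 37 named calls 7 held with any time left out. The list calls for p53 targets (adjusted p = 0.0516 without the 660 min pair), cholesterol synthesis (0.0597 without 120 min, 0.111 without 180 min, 0.0506 without the 510 min pair and 0.124 without the 660 min pair) and NF-kB genes (0.201 without 60 min, 0.0553 without 120 min, 0.0509 without the 510 min pair, 0.124 without the 660 min pair and 0.163 with the term for sampling time left out) ended. Of the 22 genes that the second pulse raised, 21 were called lower in the late than in the early window, where independent lists would share 1.94. Across the 10053 genes, which are not independent replicates, the responses correlated with a Pearson r of -0.061 (Spearman rho -0.147) at 30 min, 0.358 (0.207) at 60 min, 0.372 (0.129) at 120 min and 0.312 (0.266) at 180 min.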

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

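All tests of explanations in this part were chosen only after the result was seen. Genes and lists appear here because their effect differed, by a test of the difference itself, between the first and the second pulse or between the later and the earlier times of the second pulse. For lists that test used the preset correlation, and with an estimated correlation 0 of the 60 list calls held. In 37 groups of 4 values, 0 had a value far from the others.

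Between the pulses 376 genes differed. The first minus second difference was positive for NR4A2 (3.10), RGS2 (2.25), STEAP4 (1.84), CFLAR (1.69), F2R (1.63), IL1RN (1.503), SESN3 (1.36), TP53INP1 (1.22), and CD24 (1.21). It was also positive for TXNIP (1.17), NUSAP1 (1.04), NUPR1 (1.01), NR4A3 (1.01), SLC7A11 (0.96), NRG1 (0.94), KIF20A (0.86), CENPF (0.83), KIF11 (0.78), MMP14 (0.72), SPATA18 (0.68), RRM2B (0.64), PHGDH (0.54), STARD4 (0.52), DDB2 (0.44) and TRIM29 (0.42). The difference was negative for TLR4 (-1.40), NOG (-1.04), MLPH (-1.01), MST1R (-0.96), MYEOV (-0.91), SLCO4A1 (-0.91), RRP9 (-0.74), RRS1 (-0.70), OAS1 (-0.68), MYBBP1A (-0.64), PFAS (-0.63) and CCNE1 (-0.50). With the late window as baseline of the first pulse 340 of the 376 genes kept their direction, and it turned for others, of those named TXNIP (-0.60), SLC7A11 (-0.26) and MST1R (0.0150). List medians of the difference were 0.71 for NF-kB and cytokine genes, 0.53 for G2/M, 0.28 for p53 targets, 0.17 for cholesterol synthesis, -0.22 for nucleotide synthesis, -0.23 for ribosome biogenesis and -0.24 for G1/S.

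The later and earlier effects of the second pulse differed for 10 genes. Named among them were FST (1.80), EREG (1.64), ANGPTL4 (1.61), PHLDA1 (1.54), ITGA2 (1.42), AKAP12 (1.12) and BCL6 (-1.05). List medians were 0.76 for ErbB ligands, 0.38 for matrix and migration, 0.27 for feedback regulators, 0.14 for ribosome biogenesis, -0.13 for amino acid stress and -0.29 for FOXO targets. Among 4496 probe sets with no symbol or several, outside the main measurement, 53 differed by 2-fold between the second and the mock pulse at 600 min, against 32, 32 and 52 between neighbouring mock arrays.

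Of the called genes 294 responded more to the first pulse than to the second, with a difference above 0, and 227 of these had a second effect below 0. The difference was below 0 for 82, all with a first response below 0, and the counts were 210 and 113 with median centring and 209 and 142 with quantile normalization. The signs of the first and second response partly follow from choosing genes by their difference. The mock arm could take genes induced by handling out of the second response alone. With the 480 min array as baseline instead, the median difference over the 294 genes was 0.972 of the original (95% bootstrap interval 0.944 to 1.004). This argues against it for these genes as a set, not for single genes. This interval and the next resample genes, not arrays, so the error of the baseline arrays is left out. With the 480 min baseline 154 genes were called in place of 376. A low start array stays open: with the late window as baseline of the first pulse the ratio was 0.474 (0.422 to 0.511), an interval on both sides of the 0.5 set for the test. That baseline would also take out a first response that lasted into the late window. TXNIP, for example, was still 1.89 above the start at 480 min. The ratio therefore cannot decide on a low start array. A real loss of responsiveness after the first pulse is a candidate explanation that was not tested apart from the start array. No arm received its first EGF pulse at 480 min. An effect of the first pulse therefore cannot be told apart from one of longer time in culture without growth factors.

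Immediate early genes were higher on the mock array at 510 min than on the 480 min array, with a median of 0.52. Exchanged labels of the arrays at 510 min are argued against by the second pulse lying above the mock pulse, with a median of 0.4523 and 21 of 23 genes above 0. The medians of all probe sets were 4.80 at 480 min and 4.79 on the mock array at 510 min. The deposited values thus hold no shift of the whole array near 0.52. A shift before normalization could not be tested, because the authors' quantile normalization brings arrays to a common level and so holds the housekeeping median (0.0274) near 0. A short response to the exchange of medium is consistent with a fall that went on from mock 540 min to mock 600 min, on arrays other than those of the pattern, with a median of -0.3210 and 21 of 23 genes below 0. Traces of EGF in the mock medium were not tested apart from this.

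G2/M genes were higher than the start array at each of the 8 times after the first pulse, with medians from 0.22 at 360 min to 0.64 at 30 min. Array medians lay between 4.74 and 4.84, so the deposited values hold no shift of whole arrays near the 0.38 of G2/M in the early window. A shift before normalization could not be tested for the same reason as above, with a housekeeping median of 0.0373 in that window. A start array that stands apart for these genes alone cannot be told apart from a biological change, because there is 1 start array. The medians on the 16 later arrays ranged over 1.406 times the gap from the start array to the nearest of them, and that gap was 0.27.

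For the second pulse against the mock pulse, 24 genes were called. By the count of splits alone chance could not be excluded: 3 of the 32 splits of the 8 arrays that could be fitted gave as many, and the highest other split gave 210. That count came from 2 splits that keep the 510 min pair together on 1 side and the 540 min pair on the other, while still parting second from mock pulse at 600 and 660 min. With sampling time as a block, a pair kept on 1 side adds nothing to the contrast. These 2 splits are therefore the same fit with its sign turned. Their count points to a structure of the samples, the effect at those later times. The share of 3 in 32 thus counts 1 fit 2 times, a fit that holds the real effect, and does not measure chance. Among the 8 splits that part all 4 pairs the highest other gave 0 genes, but 8 splits are too few for a share under 0.05. Outside the splits, 21 of the 22 raised genes were called lower in the late than in the early window, in a fit whose variance also uses these 8 arrays, where independent lists would share 1.94, and all 23 immediate early genes lay above 0. For the late against the early window 1 of 35 splits, the real one, gave as many as its 1470 genes, and the highest other gave 2. This speaks against a random division of these 8 arrays. They are single arrays of 1 time series, so the count cannot exclude drift with time or chance differences between single arrays. For the mock arm against the late window the real count was 0, so all 35 splits give as many whatever their values, and the comparison says nothing about chance. The highest other split gave 65.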

How the results depend on the processing

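All alternatives here were planned, and none was chosen after the result was seen. Over all of them, the values below included, named genes stayed on the same side of the threshold in 3696 comparisons. That tally includes genes called in neither fit, whatever their direction. Named genes fell short of the threshold in 499 comparisons, newly passed it in 20 and reversed in 3. Called lists kept their direction and call in 351 comparisons and fell short in 107. For the second pulse against the mock pulse (24 genes), the stricter filter gave 8 genes, median centring 11, quantile normalization 12, the robust prior 11 and all 17 arrays in the fit 37. Leaving out 1 time gave 0 to 58. The stricter filter tests fewer genes (5475), and the cause of the other changes was not tested. For the later against the earlier effect (10 genes), the mean of probe sets gave 16, the intensity trend 16, the robust prior 32 and leaving out 1 time 0 to 26. Leaving out 1 array gave 595 to 910 genes for the early window against the start, 319 to 463 for the late window against the start, 872 to 1401 for the late against the early window, and 0 to 58 for the mock arm against the late window. For first minus second, leaving out 1 time gave 71 to 408. Testing all genes without a filter gave 332 for the late window against the start and 233 for first minus second, and the stricter filter gave 2 for the mock arm against the late window. The 8 arrays of both windows alone gave 799 with fewer arrays, and the 480 min array as baseline of the second pulse gave 154, a single array in place of 4. With the late window as baseline of the first pulse 332 genes differed, of which 97 were shared with the original 376, 340 of the 376 kept their direction, and among named genes it reversed for MST1R (0.0150), TXNIP (-0.60) and SLC7A11 (-0.26), and the cause was not tested. With an estimated correlation 0 of the 60 list calls held. The lower fold threshold of 0.58 gave 1445 genes for the first pulse and 481 for the second by its construction.

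The replicate block is the sampling time that the second and mock arms share by label, not a shared culture. Deviations from the arm means correlated between arrays of the same time with r = -0.069 at 510 min, -0.079 at 540 min, 0.147 at 600 min and 0.042 at 660 min, across genes, and the highest value with another time was lower at 600 and 660 min only (0.089 and -0.001), so the values do not pair the arrays. With no replicate block the second pulse gave 1 gene, and lists 53 calls, with 9 of the 60 ended. The other 5 counts stayed within 1.5 times. The filter removes genes that are dim on every array, while genes dim on a baseline array stay, such as IL6 at 3.63 and NR4A2 at 3.23 at the start.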

Other observations

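No test in this part was chosen after the result was seen. Interferon response genes differed one by one. In the late against the early window OAS1, an antiviral enzyme, rose by 0.69 ± 0.08 (limma adjusted p = 9.58e-05), while IRF1, a transcription factor, fell by 0.41 ± 0.10 (adjusted p = 0.0134, and 0.0550 without the 60 min array). Against the start array IFIT3 rose by 0.62 ± 0.12 in the late window (adjusted p = 0.0127). The list passed in neither contrast (2 of 10 called higher and 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.298, and 1 of 10 higher, 2 adjusted over the list alone, adjusted p = 0.348).

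Sugar and stress genes also gave single calls. The glucose transporter SLC2A1 fell by 0.51 ± 0.08 from the early to the late window (adjusted p = 6.00e-04) and PFKFB3, a regulator of glycolysis, by 0.44 ± 0.07, while the glycolysis list did not pass (2 of 15 called, 2 adjusted over the list alone, adjusted p = 0.332). TRIB3, a pseudokinase of the amino acid response, rose by 0.78 ± 0.08 in the same comparison (adjusted p = 6.36e-05). NUPR1, of the same list, fell by 0.53 ± 0.12 (adjusted p = 0.0106, and 0.0501 without the 30 min array). CEBPB, also of that list, fell by 0.47 ± 0.11 (adjusted p = 0.0117, and 0.0559 without the 60 min array or 0.0539 without the 120 min array). The amino acid stress list did not pass (2 of 13 called higher and 2 lower, 5 and 2 adjusted over the list alone, adjusted p = 0.0986). CD68, the 1 tested leukocyte marker, which epithelial cells can also express, fell by 0.42 ± 0.07.

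The median, mean and test direction of a list did not share a sign in 16 cases, and the list passed in none of them. For the mean effect of the second pulse these were nucleotide synthesis, glycolysis and basal epithelium. For the later against the earlier effect they were EGR1 targets and fibroblasts, and for the early window against the start glycolysis and fibroblasts. Housekeeping was the 1 such list for the late window against the start, and housekeeping and fibroblasts for the late against the early window. Immediate early genes, glycolysis and fibroblasts differed in this way for first minus second, and feedback regulators, EGR1 targets and NF-kB genes for the mock arm against the late window.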
